A study of Xenopus laevis with 20 samples.

How the data were processed

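The samples were 20 animal cap explants of the frog Xenopus laevis, 5 for each of 4 injections. An animal cap is the prospective ectoderm taken from a blastula. Embryos received mRNA at the stage of 2 cells, caps were taken at stage 9 and kept for 8 h in dexamethasone, the hormone that releases a protein fused to the hormone-binding part of the glucocorticoid receptor (GR). The injected messages were Pax3GR, Zic1GR, both together (the combination) or GR alone as the control. Total RNA of single explants, 100 ng each, was amplified, labelled and hybridised to Affymetrix Xenopus laevis Genome 2.0 arrays. The labels number the replicates 1 to 5 and do not say whether explants of one number shared a clutch.

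The deposited values are log2 probe set intensities. The submitters' processing notes name GCRMA and Partek, without versions, roles or order. Values lay between 0 and 16 on every array, with array medians from 6.10 to 6.30. Of 32635 probe sets, 96 control probe sets were left out of the tests. Gene symbols came from the array's annotation, which gave exactly 1 symbol to 15495 of the remaining 32539 probe sets, several to 279 and none to 16765. Of those symbols 15384 were checked by gene identifier in the reference table. Between 18949 and 19239 probe sets per array reached log2 4, the level used as background here. The number of arrays, 5 per group, limits the precision.

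Probe sets with log2 of at least 4 on at least 5 of the 20 arrays were tested, which kept 20519. A linear model with 1 mean per group was fitted with limma 3.58.1 in R 4.3.3, with moderated variances (eBayes). Each of 7 comparisons was tested, with Benjamini-Hochberg adjusted p over the probe sets tested and a threshold of 0.05. The comparisons were each injection against GR, the combination against each single factor, Pax3GR against Zic1GR, and non-additivity, the combination's effect minus the sum of the single effects on the log2 scale. "Rose" and "fell" are used only of what passed that threshold. A fold is given as a lower bound ("at least") where all 5 arrays of a group lay below log2 4, with those values set to 4, and no fold is given where both groups lay below it. Other differences are on the log2 scale.

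There were 23 gene lists, fixed in advance for the tissue, the pathways and the other cell types that a cap could hold. They covered neural plate border, neural crest, preplacodal and placode, neural plate and neurons, epidermis, multiciliated cells, ionocytes, mucus-secreting cells, hatching gland, cement gland, mesoderm, endoderm, retinoic acid metabolism and binding, Hox and caudal genes, the BMP, Wnt, FGF, Notch and Hedgehog pathways, glucocorticoid response, stress and p53, cell division, and germ layer specification and maternal genes. Each gene entered by its probe set with the highest mean, which gave 8397 named genes. Lists were compared with all other named genes by camera (limma) at its preset correlation of 0.01, and again with an estimated correlation, adjusted over the 161 tests of 23 lists in 7 comparisons. At the preset correlation the numbers of lists called were 15 (Pax3GR against GR), 17 (Zic1GR against GR), 13 (the combination against GR), 5 (against Pax3GR), 13 (against Zic1GR), 9 (Pax3GR against Zic1GR) and 15 (non-additivity). With an estimated correlation they were 1, 1, 2, 1, 6, 3 and 4. Calls within a list are given over all probe sets tested and adjusted over the list alone.

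Genes were named by a rule. It took pax3 and zic1, the 12 largest rises and 8 largest falls against GR (6 and 6 in the other comparisons) among called genes whose 5 values in one group all lay above the 5 of the other, and from each list up to 4 called members with the smallest adjusted p and 1 member not called with the highest mean. For non-additivity the condition on the 5 values was not applied. The genes snai2.L and sox9.L lie outside that rule and were chosen after their values were seen. Groups, comparisons, tests, lists, the rule for named genes and all alternatives but 2 were set before the data were examined. The alternatives were other filters, thresholds and scalings, other handling of low values, of several probe sets per gene and of probe sets open to cross-hybridisation, another variance model, array weights, the groups of a comparison alone, replicate number as a block, other list tests, GR arrays split between comparisons, and each array left out in turn. Of those added after the data were seen, one left out together the array of each group that correlated least with its group. The other tested non-additivity only where the sum of the single effects lay between log2 4 and 15.33, the highest group mean. Fits that left out an array filtered the probe sets again, at log2 4 on at least 5 of the arrays left. The fit with a replicate block called 10264, 10513 and 9136 probe sets for Pax3GR, Zic1GR and the combination against GR. It was set in advance that replicate numbers were not used in the tests above, and they did not pair the samples throughout. Of 30 pairs of arrays with one number in 2 groups, 8 had correlated residuals above 0.1, 12 lay below 0, and 6 matched best with their own number. Between Pax3GR and the combination the correlations were 0.35, 0.326 and 0.466 for replicates 1, 2 and 4, and 0.0416 and -0.0193 for replicates 3 and 5. Between Zic1GR and the combination replicate 5 had 0.427.

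The fit was tested on simulated data with known changes in 100 of 20519 probe sets per size. For Pax3GR against GR it recovered 54, 88, 94 and 99 of 100 changes of log2 1, 2, 4 and 8, and called 26 unchanged probe sets. For non-additivity it recovered 34, 67, 89 and 99 and called 17 unchanged ones. There each probe set had the same spread in all groups and few probe sets changed. In the data 10321 of 20519 were called for Pax3GR against GR, so these rates need not hold for the data. In a simulated Pax3GR comparison of 8397 named genes, a list of 25 members shifted by log2 1 was called and no other list was. The simulated genes varied independently of each other, and p was adjusted over 23 lists in that comparison alone. The simulation therefore does not show how often lists are called wrongly when their members vary together.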

Results

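Transcripts were measured in 20 single animal cap explants on 20 arrays, 5 each from embryos injected with Pax3GR, Zic1GR, the combination of both, or the GR control. Between 18949 and 19239 of 32539 probe sets reached log2 4 on each array. The first principal component held 46.0% of the variance and set the 5 GR arrays apart from the 15 injected ones, and the second held 20.2% and set Zic1GR apart from the rest. Explants of one injection were not alike. The lowest mean correlation of an array with the rest of its group was 0.963 for GR replicate 3, 0.881 for Pax3GR replicate 1, 0.925 for Zic1GR replicate 5 and 0.922 for combination replicate 4. Values below are mean log2 intensities ± SD with n = 5 arrays per group. The largest rises and falls named against GR separated all 5 arrays of the injected group from all 5 GR arrays. Where no count adjusted over the list alone is given for a gene list, it was the same as the count over all probe sets tested.

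**Figure D1:**
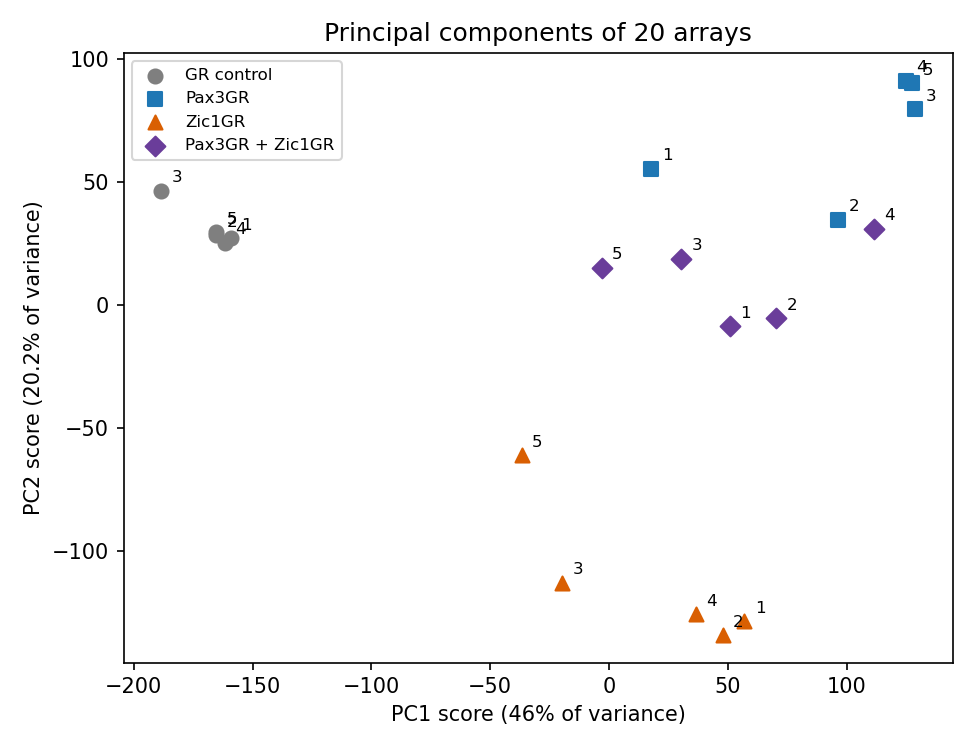
Scores of the 20 arrays on the first and second principal components, each point an array with its replicate number, coloured by injection. The axes give 46.0% and 20.2% of the variance, and Pax3GR replicate 1 lies between the other Pax3GR arrays and the GR arrays on the first.

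Each label was compared with the level of the injected genes. The pax3.S probe set Xl2.49495.3.S1_x_at lay at 2.36 ± 0.10 in GR, 13.27 ± 0.044 in Pax3GR, 10.01 ± 1.14 in Zic1GR and 12.92 ± 0.079 in the combination. The zic1.S probe set Xl2.1796.1.S2_at lay at 7.69 ± 0.83, 13.98 ± 0.12, 12.56 ± 0.50 and 13.78 ± 0.17 in the same order. Thus zic1.S rose by 6.30 with Pax3GR alone (adjusted p = 2.06e-11), and pax3.S rose by at least 64.2-fold with Zic1GR alone (adjusted p = 1.27e-11). Of the 5 pax3.L probe sets, Xl2.45266.1.S2_at rose from 2.23 to 12.93 with Pax3GR and 11.50 with Zic1GR. The probe set Xl2Affx.25.1.S1_at rose from 2.28 to 7.72 and 3.68 (for Zic1GR adjusted p = 0.0171, or 0.0539 and 0.0513 without Zic1GR replicate 1 or 4). The remaining 3 were not called with Pax3GR, and 2 of them fell with Zic1GR. Those were Xl2.54870.1.S1_at, from 9.45 to 8.12 (adjusted p = 0.00972), and Xl2.45055.1.S1_at, from 14 to 13.61 (adjusted p = 0.0251, not called without GR replicate 2 or 4 or Zic1GR replicate 3 or 4, at 0.0523 to 0.0777). The last, Xl2.45266.2.S1_at, lay at 13.56 in GR and 13.36 in Zic1GR (adjusted p = 0.0893). The labels do not say which probe sets the injected messages match. Where a factor was injected, the levels of its own gene therefore do not tell injected from native transcripts. Explants with Pax3GR alone received no zic1 message, and those with Zic1GR alone no pax3 message. The rises of zic1.S and pax3.S there were thus not of injected message.

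Pax3GR was compared with GR to find the transcripts that differ when Pax3 is active. Genes of the hatching gland, the neural plate border and the neural plate were higher, and genes of epidermis and its specialised cells were lower. Of these list calls by camera only that of the hatching gland stayed with an estimated correlation. The hatching gland protease astl3a.1.L (Xl2.120.1.S1_at) rose from 2.02 ± 0.023 to 14.66 ± 0.13, at least 1620-fold (adjusted p = 1.2e-17). The secreted ligand wnt8a.L (Xl2.49.1.S1_a_at) rose from 2.20 ± 0.07 to 13.21 ± 0.24, at least 592-fold. The BMP antagonist chrd.1.S (Xl2.3549.1.S1_a_at) rose from 2.27 ± 0.027 to 11.52 ± 0.34, at least 183-fold. The crest transcription factor foxd3.L (Xl2.525.1.S1_at) rose from 2.78 ± 0.024 to 10.66 ± 0.47, at least 101-fold. The ventral BMP target szl.L (Xl2.620.1.S1_at), which encodes sizzled, fell from 14.27 ± 0.088 to 2.26 ± 0.058, at least 1240-fold lower (adjusted p = 4.12e-11). In all, 10321 of 20519 probe sets differed by limma, 5611 higher and 4710 lower, and 6330 of them by at least 2-fold (2959 higher and 3371 lower).

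In the neural plate border list, which holds pax3 and zic1 themselves, 15 of 24 members rose and 1 fell (16 and 1 adjusted over the list alone, camera adjusted p = 2.28e-06, and adjusted p = 0.055 with an estimated correlation). Among them zic2.L rose by 8.39 log2 and tfap2b.L by 9.20. In the neural crest list 19 of 37 members rose and 5 fell (20 and 5 adjusted over the list alone, camera adjusted p = 0.00924, and adjusted p = 0.338 with an estimated correlation). There the protease gene mmp14.L rose by 6.48 and sox8.L by 3.96, while the chemokine gene cxcl12.L fell by at least 19.3-fold. The genes snai2.L and sox9.L, central regulators of crest that were chosen after their values were seen, rose by 2.88 and 2.57 (adjusted p = 0.00317 and 6.74e-05). Of the neural plate and neuron genes 21 of 30 members rose and 2 fell (camera adjusted p = 3.56e-06, and adjusted p = 0.118 with an estimated correlation), with six6.L, an eye field factor, at 10.78 ± 1.19 against 1.68 ± 0.014 and nes.S at 9.95 ± 1.12 against 2.45 ± 0.032. Hatching gland genes went the same way, as 7 of 13 members rose and 1 fell (camera adjusted p = 0.00215, and adjusted p = 0.034 with an estimated correlation), and the list holds pax3. The protease gene xa-1.L reached 14.34 ± 0.13 from 1.99 ± 0.021.

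For the epidermis 4 of 36 members rose and 26 fell (camera adjusted p = 1.45e-05, and adjusted p = 0.291 with an estimated correlation). Here tp63.S, a regulator of basal epidermis, fell by at least 39.3-fold and bmp4.S fell by 2.21, while the keratin krt70.S was 14.91 ± 0.093 against 15.06 ± 0.035 (adjusted p = 0.0802). Genes of multiciliated cells were lower, and 2 of 25 members rose and 22 fell (2 and 23 adjusted over the list alone, camera adjusted p = 5.28e-06, and adjusted p = 0.332 with an estimated correlation). The cilium regulator rfx2.S fell by 2.27 and foxj1.L fell to below log2 4 on 4 of 5 arrays, by at least 8.06-fold without Pax3GR replicate 1. That array had a list mean of 10.56, near the 10.9 to 11.92 of GR, where the lowest Pax3GR array had 5.978. Of ionocyte genes 1 of 17 members rose and 13 fell (camera adjusted p = 3.06e-06, and adjusted p = 0.113 with an estimated correlation), with the anion exchanger slc26a4.3.L at 2.12 ± 0.034 against 7.75 ± 0.56, at least 13.4-fold lower, and with list means of 5.914 to 7.843 in Pax3GR, highest in replicate 1, against 10.24 to 11.17 in GR. Among genes of mucus-secreting cells 0 of 7 members rose and 6 fell (camera adjusted p = 0.00154, and adjusted p = 0.156 with an estimated correlation), foxa1.L by at least 7.33-fold and agr2.L from 13.02 ± 0.56 to 7.68 ± 0.96. The endoderm list also fell, as 0 of 9 members rose and 5 fell (camera adjusted p = 0.0196, and adjusted p = 0.0893 with an estimated correlation). Its fallen members included foxa1.L, gata5.S (at least 10.1-fold lower) and hhex.L.

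Several signalling lists moved with Pax3GR. On the BMP list 5 of 29 members rose and 17 fell (camera adjusted p = 0.000134, and adjusted p = 0.113 with an estimated correlation). The ligand gene bmp4.S and both copies of sizzled fell, and the antagonist genes chrd.1.S and nog.L, on the same list, rose by at least 183-fold and at least 69-fold. Wnt genes were higher, and 18 of 29 members rose and 2 fell (19 and 2 adjusted over the list alone, camera adjusted p = 5e-05, and adjusted p = 0.118 with an estimated correlation), with rspo2.L, a Wnt enhancer, up by 6.13. Of FGF genes 16 of 22 members rose and 2 fell (camera adjusted p = 3.39e-05, and adjusted p = 0.131 with an estimated correlation), fgfr4.L by 4.58 and the feedback inhibitor spry2.S by at least 13.1-fold. For the Hedgehog list 6 of 7 members rose and 0 fell (camera adjusted p = 0.000557, and adjusted p = 0.156 with an estimated correlation), and gli2.L rose by at least 14.6-fold. On the mesoderm list 18 of 29 members rose and 3 fell (camera adjusted p = 0.000461, and adjusted p = 0.0874 with an estimated correlation). Its risen members included wnt8a.L, chrd.1.S, nog.L and fgf8.L, secreted signals that also act in neural induction and patterning, and the posterior gene evx1.L, up by at least 183-fold. No tbxt or actc1 probe set passed 5.42 on an injected array, or 2.55 on a GR array. Cell division genes were higher, as 29 of 60 members rose and 3 fell (camera adjusted p = 0.00268, and adjusted p = 0.37 with an estimated correlation). Among them gmnn.S, which the neural plate and neuron list also holds, rose by 1.43 and the replication licensing gene cdt1.L by 0.98.

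Camera did not call the other lists in Pax3GR. These were preplacodal and placode (10 up and 8 down of 26, adjusted p = 0.917), where the median change was -0.0222 and the mean 0.066, and retinoic acid (5 up and 2 down of 16, adjusted p = 0.558). Nor did it call Hox and caudal genes (4 up and 3 down of 10, adjusted p = 0.558), cement gland genes (2 up and 6 down of 10, adjusted p = 0.085, or 0.0427 without combination replicate 4) or Notch genes (5 up and 4 down of 20, adjusted p = 0.671). The rest were glucocorticoid response (3 up and 8 down of 22, adjusted p = 0.156), stress and p53 (5 up and 7 down of 23, adjusted p = 0.342) and maternal genes (6 up and 2 down of 12, adjusted p = 0.33). The endoderm call was lost without any single GR array, with adjusted p from 0.0691 to 0.0899. The filter was repeated there, so any member above log2 4 on the 5 GR arrays alone left the test. That loss therefore does not show that the call rested on a single GR array. When 1 probe set stood for each symbol, which tests fewer, 4438 genes differed.

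**Figure D2:**
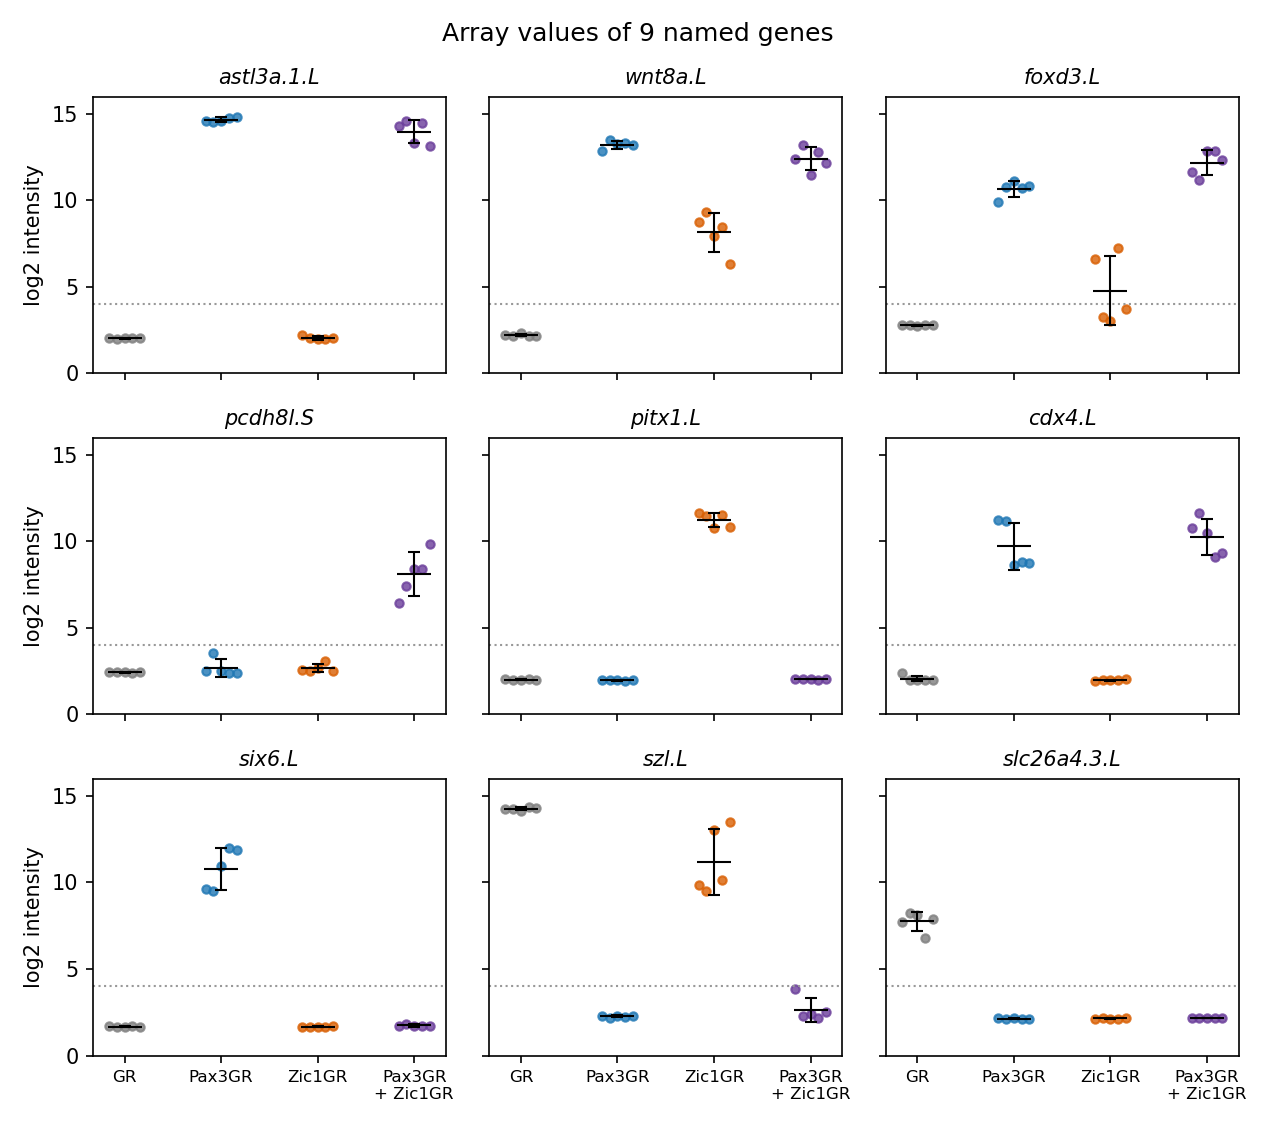
Log2 intensity of 9 named genes on each of the 20 arrays, by injection, with the mean and SD of 5 arrays (bars) and log2 4 dotted. The gene astl3a.1.L lies at 14.66 in Pax3GR and 13.97 in the combination, pitx1.L at 11.25 with Zic1GR alone, and pcdh8l.S at 8.10 in the combination alone.

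Zic1GR was compared with GR in the same way, for Zic1. Placode, neural plate and retinoic acid genes were higher, and Hox genes and those of ionocytes and multiciliated cells were lower. Only the placode call stayed with an estimated correlation. The homeobox gene pitx1.L (Xl2.522.1.S1_at), expressed in anterior placodes and cement gland, rose from 2.02 ± 0.02 to 11.25 ± 0.41, at least 153-fold (adjusted p = 6.33e-19). The water channel gene aqp3.L (Xl2.9137.1.S1_at) rose from 1.87 ± 0.051 to 14.14 ± 0.25, at least 1130-fold. The gene crx.L (Xl2.511.1.S1_at), a retinal and anterior neural homeobox gene, rose from 2.12 ± 0.15 to 13.85 ± 0.14, at least 924-fold. The lipocalin ptgds.S (Xl2.47287.1.S1_at), which can carry retinoids, rose from 1.73 ± 0.19 to 13.20 ± 0.48, at least 588-fold. The hindbrain gene hoxa2.L (Xl2.12098.1.S1_at) fell from 10.32 ± 0.48 to 3.03 ± 1.14 (adjusted p = 9.69e-08). Of 20519 probe sets 10549 differed by limma, 5878 higher and 4671 lower, 6121 of them by at least 2-fold (2908 higher and 3213 lower).

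In the preplacodal and placode list 18 of 26 members rose and 3 fell (camera adjusted p = 1.45e-05, and adjusted p = 0.0092 with an estimated correlation). Its members hesx1.L, an anterior pituitary and placode factor, and the proneural gene neurog2.S rose to 9.77 ± 1.20 and 9.096 ± 1.19 from below log2 4, and irx1.L rose by 7.05. The retinoic acid list rose, as 8 of 16 members rose and 3 fell (9 and 3 adjusted over the list alone, camera adjusted p = 0.0382, and adjusted p = 0.113 with an estimated correlation), among them the receptor gene rarg.S by 1.14 and cyp26c1.S, a retinoic acid hydroxylase, to 12.59 ± 0.77, while rxra.L fell by at least 2.67-fold. Hox and caudal genes fell, and 1 of 10 members rose and 6 fell (camera adjusted p = 0.00141, and adjusted p = 0.113 with an estimated correlation), with hoxa2.S at least 43.2-fold lower and the Hox cofactor meis3.L lower by 1.41. The caudal gene cdx2.L fell by at least 29.5-fold to 2.10 ± 0.043, or by at least 45.8-fold without GR replicate 3. For neural plate and neuron genes 22 of 30 members rose and 0 fell (camera adjusted p = 2.04e-06, and adjusted p = 0.113 with an estimated correlation), sox3.S by 2.43 and otx2.L, a forebrain factor, by 4.25. On the neural plate border list 16 of 24 members rose and 5 fell (16 and 6 adjusted over the list alone, camera adjusted p = 0.00506, and adjusted p = 0.214 with an estimated correlation), zic2.L by 6.88 and tfap2b.L by 5.99. Of crest genes 22 of 37 members rose and 8 fell (camera adjusted p = 0.0196, and adjusted p = 0.37 with an estimated correlation), with mmp14.L up by 6.197, sox8.L by 3.85 and cxcl12.L by 1.84. The value of snai2.L was 8.20 ± 2.01 against 7.57 ± 1.15 (adjusted p = 0.494).

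Ionocyte genes fell with Zic1GR, as 0 of 17 members rose and 16 fell (camera adjusted p = 1.69e-08, and adjusted p = 0.0708 with an estimated correlation), and slc26a4.3.L fell from 7.75 ± 0.56 to 2.14 ± 0.039. In the multiciliated list 1 of 25 members rose and 21 fell (1 and 22 adjusted over the list alone, camera adjusted p = 6.21e-06, and adjusted p = 0.335 with an estimated correlation), rfx2.S among them by 2.18 lower. Array means of that list ran from 6.631 to 9.374 in Zic1GR. Epidermal genes were split, and 7 of 36 members rose and 11 fell (camera adjusted p = 0.0347, and adjusted p = 0.601 with an estimated correlation), with tp63.S at 3.85 ± 0.73 and bmp4.S at 12.80 ± 0.36 against 13.00 ± 0.22 (adjusted p = 0.485). Genes of mucus-secreting cells had few calls, as 0 of 7 members rose and 2 fell (camera adjusted p = 0.0216, and adjusted p = 0.302 with an estimated correlation), and agr2.L was 12.58 ± 0.72 (adjusted p = 0.565). For endoderm 1 of 9 members rose and 5 fell (camera adjusted p = 0.0358, and adjusted p = 0.113 with an estimated correlation), with gata5.S lower by 2.71 and a2m.S up by 1.98.

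On the mesoderm list 18 of 29 members rose and 3 fell (19 and 3 adjusted over the list alone, camera adjusted p = 9.26e-05, and adjusted p = 0.0638 with an estimated correlation), with chrd.1.S, nog.L, wnt8a.L and gsc.L, an organiser and head mesoderm gene, up by at least 104-fold, at least 38.3-fold, at least 17.8-fold and at least 6.45-fold. FGF genes rose, as 13 of 22 members rose and 1 fell (16 and 1 adjusted over the list alone, camera adjusted p = 2.99e-05, and adjusted p = 0.129 with an estimated correlation), fgf8.L by 4.21 and dusp5.S by 2.32. Of Hedgehog genes 6 of 7 members rose and 0 fell (camera adjusted p = 0.00383, and adjusted p = 0.243 with an estimated correlation), gli2.L by at least 11.2-fold. On the BMP list 4 of 29 members rose and 15 fell (camera adjusted p = 0.0162, and adjusted p = 0.288 with an estimated correlation), where szl.L fell to 11.21 ± 1.91 from 14.27 ± 0.088. In the cell division list 36 of 60 members rose and 4 fell (37 and 4 adjusted over the list alone, camera adjusted p = 0.000447, and adjusted p = 0.307 with an estimated correlation), gmnn.S by 1.23. Of stress and p53 genes 5 of 23 members rose and 9 fell (camera adjusted p = 0.0441, and adjusted p = 0.252 with an estimated correlation), with jun.L and cdkn1a.L lower by at least 3.23-fold and at least 3.39-fold.

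Not called with Zic1GR were hatching gland (7 up and 3 down of 13, adjusted p = 0.222), with astl3a.1.L at 2.05 ± 0.095, and cement gland (4 up and 0 down of 10, adjusted p = 0.143). Nor were Wnt (14 up and 6 down of 29, 14 and 7 adjusted over the list alone, adjusted p = 0.259), Notch (7 up and 5 down of 20, 8 and 5 adjusted over the list alone, adjusted p = 0.624), glucocorticoid response (3 up and 10 down of 22, adjusted p = 0.0941) and maternal genes (5 up and 1 down of 12, adjusted p = 0.23). Without any single GR array the calls of the mucus-secreting, endoderm and stress lists were lost, with adjusted p of 0.109 to 0.13, 0.118 to 0.15 and 0.0618 to 0.0976. With the filter repeated, members above log2 4 on the 5 GR arrays alone were not tested there. These losses therefore do not show that the calls rested on a single GR array. The endoderm and stress calls were also lost without Pax3GR replicate 1 (0.0527 and 0.0556). The stress call was further lost without Zic1GR replicate 1, 2 or 4 (0.0507, 0.0542 and 0.0572), and the epidermis call without Zic1GR replicate 1 or 4 (0.0579 and 0.064). The retinoic acid call was lost without Zic1GR replicate 5 (0.0821) or with a replicate block (0.0518). Among symbols with 1 probe set each, 4622 differed.

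**Figure D3:**
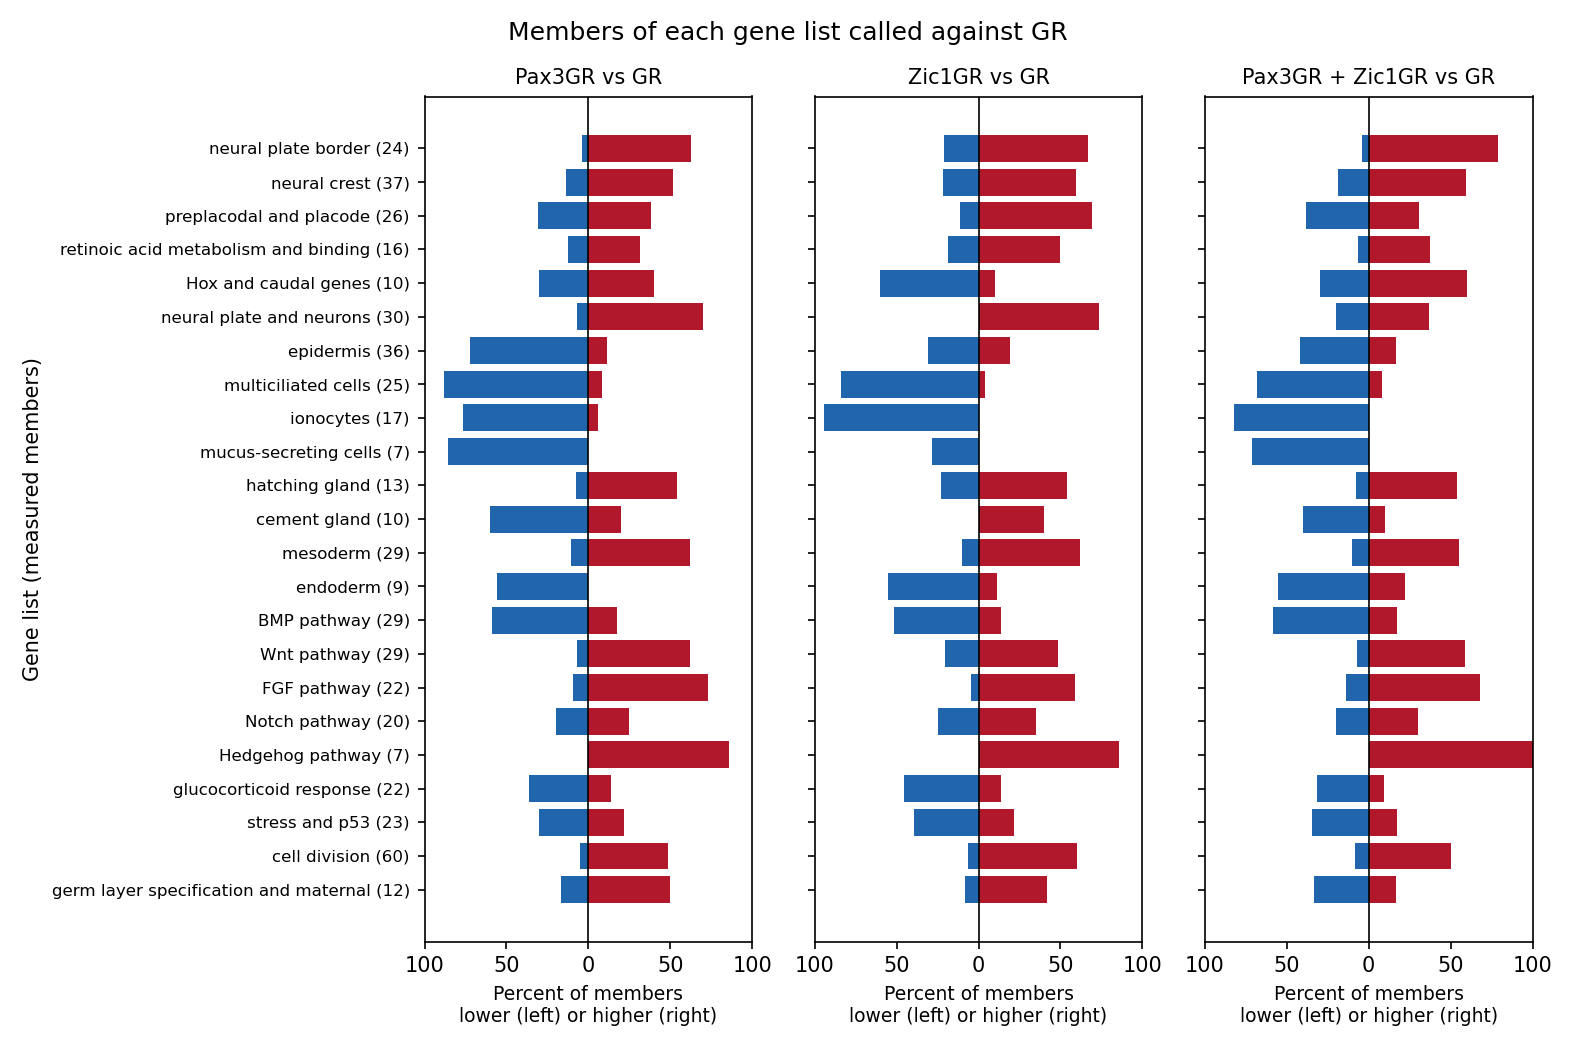
Percent of measured members of each of the 23 lists that were higher (right, red) or lower (left, blue) than GR with adjusted p below the threshold, one panel per injection, with measured members in brackets. Ionocyte genes were lower in 13, 16 and 14 of 17 members, and placode genes were higher in 18 of 26 with Zic1GR against 10 and 8 elsewhere.

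The combination was compared with GR for the joint effect of both factors. Neural plate border, crest and hatching gland genes were higher, and genes of ionocytes, multiciliated cells and mucus-secreting cells were lower. With an estimated correlation the border and hatching gland calls stayed and the others were lost. The border list holds pax3 and zic1, and the hatching gland list holds pax3. Both calls included these injected genes, so part of each may be of injected message. The crest factor foxd3.L rose from 2.78 ± 0.024 to 12.17 ± 0.73, at least 288-fold (adjusted p = 3.45e-09), and its other copy foxd3.S (Xl2.523.1.S1_at) from 2.52 ± 0.027 to 10.71 ± 1.60, at least 104-fold. The crest regulators snai2.L and sox9.L, chosen after their values were seen, rose to 13.29 ± 0.24 and 10.68 ± 0.72, 52.8-fold and 34.9-fold (adjusted p = 7.46e-06 and 2.66e-08). The protease astl3a.1.L rose to 13.97 ± 0.68, at least 1000-fold, and szl.L fell to 2.64 ± 0.68, at least 1240-fold lower. Of 20519 probe sets 9197 differed by limma, 5041 higher and 4156 lower, 5353 of them by at least 2-fold (2510 higher and 2843 lower).

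On the neural plate border list 19 of 24 members rose and 1 fell (21 and 2 adjusted over the list alone, camera adjusted p = 1.69e-08, and adjusted p = 0.034 with an estimated correlation), zic2.L by 8.39 and msx1.S by 1.07. The border and hindbrain homeobox gene lmx1b.1.S, on no list, reached 12.34 ± 0.15 from 2.10 ± 0.041. For neural crest 22 of 37 members rose and 7 fell (camera adjusted p = 0.000894, and adjusted p = 0.23 with an estimated correlation), with sox8.L up by 5.81 and mmp14.L by 6.68. Hatching gland genes rose, as 7 of 13 members rose and 1 fell (7 and 2 adjusted over the list alone, camera adjusted p = 0.00197, and adjusted p = 0.034 with an estimated correlation). The Wnt list rose too, and 17 of 29 members rose and 2 fell (18 and 2 adjusted over the list alone, camera adjusted p = 1.87e-05, and adjusted p = 0.113 with an estimated correlation), with wnt8a.L at 12.39 ± 0.67 and rspo2.L up by 6.80. Of Hedgehog genes 7 of 7 members rose and 0 fell (camera adjusted p = 0.00014, and adjusted p = 0.121 with an estimated correlation), gli2.L by at least 22-fold. In the FGF list 15 of 22 members rose and 3 fell (16 and 3 adjusted over the list alone, camera adjusted p = 0.00194, and adjusted p = 0.271 with an estimated correlation), fgfr4.L by 4.97, while dusp5.S, a phosphatase that limits FGF signalling, fell by 3.90. Of mesoderm list members 16 of 29 members rose and 3 fell (16 and 4 adjusted over the list alone, camera adjusted p = 0.00301, and adjusted p = 0.121 with an estimated correlation), nog.L by at least 61.6-fold and evx1.L by at least 261-fold. For cell division 30 of 60 members rose and 5 fell (camera adjusted p = 0.00141, and adjusted p = 0.356 with an estimated correlation), gmnn.S by 1.096.

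Ionocyte genes fell in the combination, as 0 of 17 members rose and 14 fell (camera adjusted p = 1.69e-08, and adjusted p = 0.0708 with an estimated correlation), with array means of 5.312 to 6.897. Multiciliated genes fell, as 2 of 25 members rose and 17 fell (2 and 21 adjusted over the list alone, camera adjusted p = 4.83e-05, and adjusted p = 0.37 with an estimated correlation), with array means of 6.56 to 9.527. Of epidermal genes 6 of 36 members rose and 15 fell (6 and 17 adjusted over the list alone, camera adjusted p = 0.00414, and adjusted p = 0.487 with an estimated correlation), bmp4.S lower by 2.13. For mucus-secreting cells 0 of 7 members rose and 5 fell (camera adjusted p = 0.000917, and adjusted p = 0.139 with an estimated correlation), with agr2.L at 7.43 ± 1.52. On the BMP list 5 of 29 members rose and 17 fell (6 and 18 adjusted over the list alone, camera adjusted p = 0.000367, and adjusted p = 0.121 with an estimated correlation), szl.S among them at 2.89 ± 0.073 against 14.24 ± 0.14. Camera did not call placode (8 up and 10 down of 26, adjusted p = 0.397), retinoic acid (6 up and 1 down of 16, adjusted p = 0.308, or 0.0499 without GR replicate 2) or Hox genes (6 up and 3 down of 10, adjusted p = 0.239). It did not call neural plate (11 up and 6 down of 30, 12 and 6 adjusted over the list alone, adjusted p = 0.138, or 0.0397 without combination replicate 3) or cement gland genes (1 up and 4 down of 10, adjusted p = 0.094, or 0.0361 without combination replicate 5). Also not called were endoderm (2 up and 5 down of 9, adjusted p = 0.0951), Notch (6 up and 4 down of 20, adjusted p = 0.962, with a mean of -0.0432 and a median of 0.0577), glucocorticoid response (2 up and 7 down of 22, adjusted p = 0.0927), stress (4 up and 8 down of 23, adjusted p = 0.138) and maternal genes (2 up and 4 down of 12, adjusted p = 0.397). Tested by 1 probe set per symbol, 3986 genes differed.

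**Figure D4:**
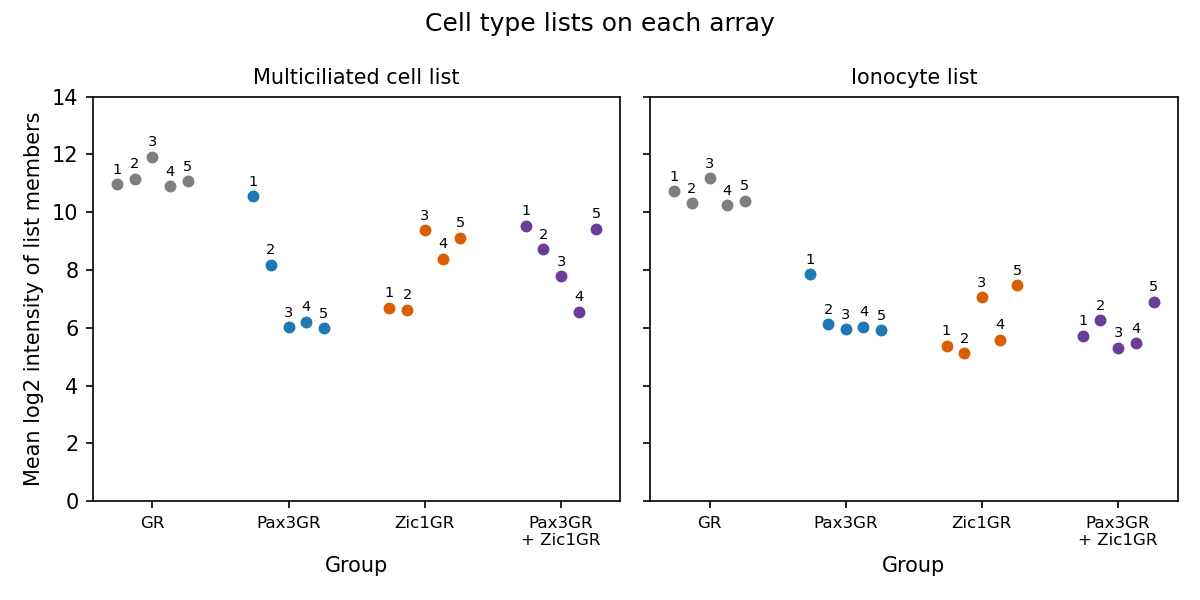
Mean log2 intensity of the members of the multiciliated (left) and ionocyte (right) lists on each array, by injection, with replicate numbers. The multiciliated mean was 10.56 in Pax3GR replicate 1 and 5.978 in the lowest Pax3GR array, against 10.9 to 11.92 in GR.

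The combination was compared with Pax3GR for what Zic1GR added. Neural plate genes were lower. The cell adhesion gene pcdh8l.S (Xl2.4847.1.S1_at) rose from 2.68 ± 0.50 to 8.10 ± 1.27, at least 17.2-fold (adjusted p = 1.58e-07), and foxa2.L (Xl2.40286.1.A1_at), a floor plate and endoderm factor, from 2.40 ± 0.37 to 8.15 ± 0.996, at least 17.8-fold. The eye field factor six6.L fell from 10.78 ± 1.19 to 1.74 ± 0.06, at least 110-fold lower (adjusted p = 2.37e-11), and nes.S from 9.95 ± 1.12 to 3.22 ± 1.14. By limma 2106 of 20519 probe sets differed, 878 higher and 1228 lower. In the neural plate list 0 of 30 members rose and 15 fell (0 and 18 adjusted over the list alone, camera adjusted p = 5.67e-11, and adjusted p = 0.0468 with an estimated correlation), with sox3.S lower by 3.04. Epidermal genes were higher, as 4 of 36 members rose and 0 fell (camera adjusted p = 0.000105, and adjusted p = 0.344 with an estimated correlation), tp63.S by at least 10.9-fold. Of FGF genes 0 of 22 members rose and 7 fell (2 and 9 adjusted over the list alone, camera adjusted p = 0.0028, and adjusted p = 0.288 with an estimated correlation), spry2.S and dusp5.S lower by 2.39 and 3.59. Maternal list genes fell, and 0 of 12 members rose and 4 fell (0 and 5 adjusted over the list alone, camera adjusted p = 0.000731, and adjusted p = 0.0874 with an estimated correlation). For placode genes 0 of 26 members rose and 6 fell (0 and 9 adjusted over the list alone, camera adjusted p = 0.0377, and adjusted p = 0.123 with an estimated correlation).

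Of the remaining lists in that comparison, crest had 10 up and 5 down of 37, 11 and 6 adjusted over the list alone, adjusted p = 0.104, with sox8.L up by 1.85 and sox9.L by 2.56, and the border list had 2 up and 0 down of 24, adjusted p = 0.31. The multiciliated list had 0 up and 0 down of 25, adjusted p = 0.0652. The other 15 had adjusted p of 0.0573 to 0.917, and the median, the mean and the test differed in sign for retinoic acid, mucus-secreting cells, Wnt, glucocorticoid response and cell division. The placode call was lost without Pax3GR replicate 1 (0.0601) or combination replicate 2 (0.0753) or 4 (0.0956). The multiciliated list was called without Pax3GR replicate 1 (0.0002) or 2 (0.0469) or combination replicate 3 (0.0194) or 4 (0.006). Crest was called without Pax3GR replicate 3 (0.0258) or combination replicate 3 (0.0347), and BMP without Zic1GR replicate 4 (0.0452) or combination replicate 3 (0.0176) or 4 (0.0235). Mesoderm was called without combination replicate 1 (0.0444) and cement gland without combination replicate 4 (0.0407). The count was the least steady of the 7, at 3038 without Pax3GR replicate 1, and 1226 and 1272 without Pax3GR replicates 4 and 5. It was 1373 and 1401 without combination replicates 3 and 5, 787 with these 2 groups alone, and 1330 at a change of at least 2-fold (515 higher and 815 lower). Array weights gave 4914, and 908 genes differed by 1 probe set per symbol.

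The combination was compared with Zic1GR for what Pax3GR added. Hatching gland, neural plate border, Wnt and Hox genes were higher, and placode, cement gland and retinoic acid genes were lower. All of these but the cement gland call stayed with an estimated correlation. The hatching gland and border lists hold pax3, which Zic1GR explants did not receive. Their calls included it, so part of each may be of injected message. The posterior gene cdx4.L (Xl2.26888.1.S2_at) rose from 1.99 ± 0.032 to 10.25 ± 1.06, at least 76-fold (adjusted p = 2.55e-09), and astl3a.1.L from 2.05 ± 0.095 to 13.97 ± 0.68, at least 1000-fold. The T-box gene tbx1.L (Xl2.51448.1.S1_at), active in pharyngeal and ear development, rose from 2.53 ± 0.40 to 11.02 ± 0.77, at least 130-fold. The genes pitx1.L and hesx1.L fell by at least 153-fold and at least 54.6-fold. The gene lrat.L (Xl2.47677.1.S1_at), whose enzyme stores retinol as esters, fell by at least 107-fold. By limma 2728 probe sets differed, 1446 higher and 1282 lower, 1778 of them by at least 2-fold (992 higher and 786 lower).

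Placode genes showed the smallest p of these lists, as 0 of 26 members rose and 16 fell (0 and 18 adjusted over the list alone, camera adjusted p = 6.66e-21, and adjusted p = 6.72e-06 with an estimated correlation). Of Hox and caudal genes 9 of 10 members rose and 0 fell (camera adjusted p = 9.86e-12, and adjusted p = 0.00415 with an estimated correlation), with hoxa2.L at 8.21 ± 1.21 against 3.03 ± 1.14 and meis3.L up by 2.65. In the neural plate border list 13 of 24 members rose and 2 fell (14 and 2 adjusted over the list alone, camera adjusted p = 2.95e-08, and adjusted p = 0.034 with an estimated correlation), tfap2b.L by 2.72. Wnt genes were higher, as 16 of 29 members rose and 3 fell (19 and 5 adjusted over the list alone, camera adjusted p = 2.95e-08, and adjusted p = 0.0479 with an estimated correlation), wnt8a.L by 4.23. For hatching gland 4 of 13 members rose and 1 fell (5 and 1 adjusted over the list alone, camera adjusted p = 0.00019, and adjusted p = 0.0142 with an estimated correlation). For cement gland 1 of 10 members rose and 6 fell (1 and 7 adjusted over the list alone, camera adjusted p = 9.63e-06, and adjusted p = 0.0874 with an estimated correlation), agr2.L by 5.14. Retinoic acid genes fell, as 2 of 16 members rose and 7 fell (2 and 8 adjusted over the list alone, camera adjusted p = 0.00557, and adjusted p = 0.0468 with an estimated correlation), rarg.S by 0.59. Of neural plate genes 1 of 30 members rose and 13 fell (2 and 15 adjusted over the list alone, camera adjusted p = 5.28e-06, and adjusted p = 0.121 with an estimated correlation). Of crest genes 14 of 37 members rose and 9 fell (15 and 9 adjusted over the list alone, camera adjusted p = 0.0126, and adjusted p = 0.356 with an estimated correlation), with sox8.L up by 1.95, sox9.L by 3.51 and cxcl12.L down to 3.21 ± 1.18. On the BMP list 6 of 29 members rose and 14 fell (6 and 17 adjusted over the list alone, camera adjusted p = 0.00141, and adjusted p = 0.156 with an estimated correlation), bmp4.S by 1.93. The FGF, Hedgehog and maternal lists were called as well. In FGF 1 of 22 members rose and 8 fell (camera adjusted p = 0.0328, and adjusted p = 0.413 with an estimated correlation). In Hedgehog 2 of 7 members rose and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.0423, and adjusted p = 0.376 with an estimated correlation). Among maternal genes 0 of 12 members rose and 4 fell (camera adjusted p = 0.00215, and adjusted p = 0.113 with an estimated correlation). The FGF call was lost without Zic1GR replicate 2 (0.0508) or combination replicate 3 (0.162), and the Hedgehog call without Zic1GR replicate 3 or 5 (0.0673 and 0.112) or combination replicate 2 or 4 (0.0831 and 0.0817). The other 10 lists had adjusted p of 0.204 to 0.871, the multiciliated list 0.0467 without combination replicate 4, and for ionocytes and mucus-secreting cells the test differed in sign from the median or the mean. Tested by 1 probe set per symbol, 1127 genes differed.

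Pax3GR was compared directly with Zic1GR. Placode, retinoic acid and cement gland genes were lower with Pax3GR, and Wnt, border, Hox and hatching gland genes were higher. The placode, Hox and hatching gland calls stayed with an estimated correlation, and the others were lost. The border and hatching gland calls included pax3, injected with Pax3GR only, so part of each may be of injected message. Both astl3a.1.L and tbx1.L were higher with Pax3GR, by at least 1620-fold and at least 219-fold (adjusted p = 9.09e-18 and 1.14e-13). The genes pitx1.L, lrat.L and nkx2-3.L (Xl2.1046.1.S1_at), a pharyngeal and heart homeobox gene, were lower by at least 153-fold, at least 107-fold and at least 72.2-fold. The adjusted p for nkx2-3.L was 1.37e-12, with 2.15 ± 0.093 in Pax3GR and 10.17 ± 0.95 in Zic1GR. By limma 7037 probe sets differed, 3543 higher with Pax3GR and 3494 lower, 3921 of them by at least 2-fold (2141 higher and 1780 lower). The median of all probe sets was -0.0447, and -0.148 with arrays centred on their medians, so differences are relative to those.

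Of placode genes 1 of 26 members rose and 20 fell (2 and 20 adjusted over the list alone, camera adjusted p = 6.61e-09, and adjusted p = 0.000988 with an estimated correlation), with otx2.L lower by 4.38. In the Hox and caudal list 6 of 10 members rose and 0 fell (camera adjusted p = 5.28e-06, and adjusted p = 0.0381 with an estimated correlation), meis3.L by 3.05. For the Wnt list 19 of 29 members rose and 5 fell (20 and 5 adjusted over the list alone, camera adjusted p = 1.53e-05, and adjusted p = 0.113 with an estimated correlation), wnt8a.L by 5.05. Border genes were higher, as 15 of 24 members rose and 4 fell (16 and 6 adjusted over the list alone, camera adjusted p = 0.000367, and adjusted p = 0.118 with an estimated correlation), msx1.S by 0.95. Cement gland genes were lower, as 1 of 10 members rose and 7 fell (camera adjusted p = 0.000115, and adjusted p = 0.115 with an estimated correlation), ag1.L by 3.18. Of retinoic acid genes 2 of 16 members rose and 8 fell (camera adjusted p = 0.0126, and adjusted p = 0.0707 with an estimated correlation), rarg.S by 0.61. Hatching gland genes differed too, as 8 of 13 members rose and 3 fell (8 and 4 adjusted over the list alone, camera adjusted p = 0.00496, and adjusted p = 0.0468 with an estimated correlation). For epidermis 1 of 36 members rose and 16 fell (1 and 18 adjusted over the list alone, camera adjusted p = 0.00111, and adjusted p = 0.413 with an estimated correlation). For the BMP list 4 of 29 members rose and 16 fell (7 and 17 adjusted over the list alone, camera adjusted p = 0.00215, and adjusted p = 0.178 with an estimated correlation). The gene bmp4.S, on both lists, was lower by 2.02. The other 14 lists had adjusted p of 0.159 to 0.849, and for ionocytes, endoderm and maternal genes the test differed in sign from the median or the mean. By 1 probe set per symbol 3063 genes differed, and 4516 probe sets passed an adjusted p of 0.01. Array weights raised the count of probe sets, as given with the other alternatives below.

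The combination was then set against the sum of the single effects. Genes that rose with each factor alone mostly fell short of the sum, and several genes of single factors were at background in the combination. The gene pitx1.L lay at 11.25 ± 0.41 with Zic1GR and at 2.04 ± 0.015 in the combination, a non-additivity of -7.255 with values below 4 set to 4 (adjusted p = 3.08e-16 without that). The gene six6.L lay at 10.78 ± 1.19 with Pax3GR and at 1.74 ± 0.06 in the combination, a non-additivity of -6.781 with values below 4 set to 4. Other sums lay beyond what the array can measure. For the signalling gene pnhd.L (Xl2.23480.1.S1_at), which rose by at least 745-fold and at least 429-fold with each factor and by at least 855-fold with both, the sum was 24.05, so that a shortfall was fixed by the ceiling. For the epidermal regulator tp63.S, at 3.202 ± 0.41 and 3.85 ± 0.73 with the single factors and 7.45 ± 1.41 with both, the sum was -2.245, so that an excess was fixed by the floor. Of 20519 probe sets 7510 were non-additive by limma, 3482 above the sum and 4028 below it, and 5521 by at least 2-fold (2875 above and 2646 below). Of these 7510, 6078 had a sum between log2 4 and 15.33, the highest group mean, with 2210 above it and 3868 below. The combination's mean lay between the single means in 3660 of the 7510. In 5268 both single effects were called in the same direction, and in 5266 of those the non-additivity was opposite to them (4003 of 4005 with a sum in that range). The combination was called above GR and above each single factor for 81 probe sets, and below all of them for 60. Among the former were pcdh8l.S, sox8.L, sox9.L and snai2.L, and snai2.L was above Pax3GR by 2.84 (adjusted p = 0.0186, or 0.0505 without Pax3GR replicate 4) and above Zic1GR by 5.096 (4.39 without Zic1GR replicate 3). Among the latter were dll1.L, a Notch ligand gene, at 8.75 ± 0.58 against 11.14 ± 0.21 in GR, and dusp5.S. A place above each single factor did not by itself put a gene above the sum. Of the genes just named as above each single factor, only pcdh8l.S was called above the sum (limma adjusted p = 5.43e-06). Others of the 81 probe sets were too, such as foxa2.L and znf703.S (limma adjusted p = 0.000374 and 0.000231). The rest included probe sets called below the sum and ones not called. The sums for pcdh8l.S and foxa2.L, 2.914 and 3.451, lay below log2 4. With values below 4 set to 4 their non-additivity was 4.103 and 3.763. The gene sox8.L was called below the sum (limma adjusted p = 0.00827). Neither sox9.L nor snai2.L was called non-additive (limma adjusted p = 0.221 and 0.102).

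For lists, a rise here means a value above the sum and a fall 1 below it. On the neural plate list 0 of 30 members rose and 26 fell (camera adjusted p = 1.08e-14, and adjusted p = 0.0318 with an estimated correlation). The FGF list was below the sum, as 0 of 22 members rose and 16 fell (camera adjusted p = 2.48e-07, and adjusted p = 0.0874 with an estimated correlation). So were placode genes, as 2 of 26 members rose and 18 fell (5 and 18 adjusted over the list alone, camera adjusted p = 1.85e-07, and adjusted p = 0.00229 with an estimated correlation), and mesoderm list genes, as 3 of 29 members rose and 17 fell (camera adjusted p = 5.18e-06, and adjusted p = 0.034 with an estimated correlation). Border genes (camera adjusted p = 0.0182, and adjusted p = 0.289 with an estimated correlation) numbered 4 above and 11 below. Hedgehog genes (camera adjusted p = 0.00779, and adjusted p = 0.288 with an estimated correlation) numbered 0 and 4. Cell division genes (3 and 27 adjusted over the list alone, camera adjusted p = 0.000737, and adjusted p = 0.332 with an estimated correlation) numbered 2 and 25, and maternal genes (camera adjusted p = 0.0104, and adjusted p = 0.156 with an estimated correlation) 0 and 6. Above the sum lay multiciliated genes, of which 21 of 25 members rose and 1 fell (camera adjusted p = 8.39e-07, and adjusted p = 0.291 with an estimated correlation), and ionocyte genes, of which 12 of 17 members rose and 0 fell (13 and 0 adjusted over the list alone, camera adjusted p = 4.16e-07, and adjusted p = 0.0992 with an estimated correlation). Epidermal genes lay there too, as 17 of 36 members rose and 4 fell (20 and 4 adjusted over the list alone, camera adjusted p = 0.000264, and adjusted p = 0.37 with an estimated correlation). Of BMP genes 15 of 29 members rose and 4 fell (camera adjusted p = 0.00372, and adjusted p = 0.201 with an estimated correlation). The same held for Hox genes, as 6 of 10 members rose and 1 fell (camera adjusted p = 0.000268, and adjusted p = 0.0874 with an estimated correlation). Also above it were endoderm genes, as 5 of 9 members rose and 0 fell (camera adjusted p = 0.0016, and adjusted p = 0.034 with an estimated correlation), and genes of mucus-secreting cells, as 4 of 7 members rose and 0 fell (camera adjusted p = 0.0163, and adjusted p = 0.288 with an estimated correlation). The mucus-secreting call was lost without any single GR array (0.0884 to 0.11), and the retinoic acid list was called without any of them (0.00575 to 0.0134) or Pax3GR replicate 4 (0.048). Without a GR array, members above log2 4 on the 5 GR arrays alone no longer passed the filter. Those changes therefore do not show a dependence on a single GR array. Since many sums lay beyond the array's range, lists were tested again on members with a sum between log2 4 and 15.33, which kept 9 of the 15 calls. Below the sum stayed neural plate (0 above and 20 below of 23 members, adjusted p = 1.35e-12), placode (0 and 13 of 17, 3.95e-08), FGF (0 and 14 of 19, 2.71e-06), mesoderm (1 and 11 of 20, 0.000334) and cell division genes (0 and 25 of 57, 0.000553). Above it stayed epidermis (14 and 4 of 33, 0.000508), BMP (11 and 2 of 23, 0.000431), multiciliated (8 and 1 of 12, 0.00124) and ionocyte genes (3 and 0 of 6, 0.0337). Of the 17 ionocyte members 11 had a sum below log2 4, as did 13 of the 25 multiciliated ones, which left these little room below the sum. The Hox (0.194), endoderm (0.223), mucus-secreting (0.0576), Hedgehog (0.0579) and maternal (0.0541) lists were not called in that range, nor was the border list, in the other direction (0.345). The other 8 lists had adjusted p of 0.0756 to 0.428, with a median of 0.328 and a mean of -1.46 for cement gland. By 1 probe set per symbol 3258 genes were non-additive, and 4238 probe sets passed an adjusted p of 0.01.

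Calls against GR were shared. Pax3GR and Zic1GR changed 6346 probe sets in the same direction, such as the rises of chrd.1.S and mmp14.L and the falls of slc26a4.3.L and jun.L. They changed 347 in opposite directions, such as cxcl12.L, lrat.L and meis3.L. Independent calls would share 2680 in direction. The combination shared 7281 with Pax3GR, among them szl.L and astl3a.1.L, with 2332 from independent calls and 32 opposite. It shared 6956 with Zic1GR, with 2390 from independent calls and 126 opposite. These pairs use the same GR arrays. With separate GR arrays the medians over 20 divisions were 4098, 4904 and 4364.5. Changes correlated at 0.69 (Pax3GR and Zic1GR), 0.89 (Pax3GR and the combination) and 0.785 (Zic1GR and the combination) over all probe sets. In simulations without true changes the shared GR arrays alone gave 0.498, 0.5 and 0.5, and separate GR arrays gave 0.663, 0.861 and 0.75 in the data.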

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

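Of the tests in this part, the limma comparisons and that with separate arrays for the choice of probe sets and for the interaction were set in advance. All others were chosen only after the result was seen.

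For the 77 probe sets of the genes named in the comparisons, each group's 5 values were searched for 1 value far from the others, by its gap to the nearest value as a share of the group's range. That gave 32 of 308 groups, where chance flags about 1 in 20 groups, or 15.4. In 11 of them the whole range was under 0.5 log2. GR replicate 1 was highest for cdx4.L (gap 0.944), hesx1.L (gap 0.949), hoxa2.L (gap 0.755) and msx1.S (gap 0.728), and lowest for nkx2-3.L (gap 0.718). GR replicate 3 was highest for ptgds.S (gap 0.967) and wnt8a.L (gap 0.727), and lowest for cdx2.L (gap 0.894), snai2.L (gap 0.792) and tp63.S (gap 0.833). GR replicate 4 was highest for crx.L (gap 0.795). GR replicate 5 was highest for pax3.S (Xl2.49495.3.S1_a_at) (gap 0.893). Pax3GR replicate 1 was highest for foxa2.L (gap 0.891), foxj1.L (gap 0.895) and rfx2.S (gap 0.901), and lowest for gmnn.S (gap 0.837) and tbx1.L (gap 0.738). Pax3GR replicate 2 was highest for pcdh8l.S (gap 0.899), and lowest for pax3.L (Xl2.45266.2.S1_at) (gap 0.797). Zic1GR replicate 3 was lowest for cyp26c1.S (gap 0.714). Zic1GR replicate 5 was highest for cdkn1a.L (gap 0.783), hoxa2.L (gap 0.947) and hoxa2.S (gap 0.781). Combination replicate 1 was highest for cdkn1a.L (gap 0.86) and szl.L (gap 0.805). Combination replicate 2 was highest for six6.L (gap 0.878), and lowest for xa-1.L (gap 0.771). Combination replicate 3 was highest for lrat.L (gap 0.803), and lowest for sox8.L (gap 0.884). Combination replicate 4 was lowest for gsc.L (gap 0.746). Combination replicate 5 was lowest for chrd.1.S (gap 0.712) and zic1.S (Xl2.1796.1.S2_at) (gap 0.856).

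The effect of Pax3GR differed with and without Zic1GR for 7510 probe sets, by the test of the difference itself. The control probe set for gapdh, left out of the comparisons, was higher by 2.31 log2 in Zic1GR than in GR, at 12.68 ± 0.34 against 10.36 ± 0.24 (SD, n = 5), on 5 of 5 arrays. Both gapdh genes among the probe sets tested went the same way, gapdh.L by 2.60 (limma adjusted p = 8.45e-09) and gapdh.S by 0.61 (limma adjusted p = 0.00281).

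Pax3GR replicate 1 kept multiciliated transcripts at a list mean of 10.56, where GR had 10.9 to 11.92 and the lowest Pax3GR array 5.978. Cells with the whole, unchanged profile of GR explants do not account for it: the multiciliated members kept 0.669 of their GR level, which would leave a transcript of log2 12 near 11.4, yet 5 of 2686 probe sets at 12 or more on all GR arrays lay below 4 in this array, among them both copies of sizzled, szl.L at 2.29 and szl.S at 2.77, and val.L at 2.41. A mislabelled combination sample does not account for it either, since 7 of the 11 probe sets present on the other Pax3GR arrays and below 4 in the combination were present here (63.6%), among them six6.L at 9.61. In combination arrays left out of that choice at most 7.14% were. Less active Pax3GR could be the source, since 0.315 of the falls of the other 4 arrays was kept, the lowest of the 15 injected arrays (next 0.613, Zic1GR replicate 5). The share of rises kept, 0.854, does not single it out, with 0.842 in Zic1GR replicate 5 and 0.862 in combination replicate 5. Another could be poorer RNA or labelling, since the actin control gap of 1.28 was wider than the widest other, 0.99, though the gapdh control gap of 3.834 was not the widest (4.68, combination replicate 3, with a multiciliated mean of 7.777). These 2 cannot be told apart here. A difference between clutches was not tested, nor were uninjected cells that had themselves lost transcripts such as sizzled.

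Non-additivity opposite to shared single effects was found in 5266 of 5268 probe sets. The array's floor and ceiling do not account for all of it: of 18401 probe sets whose summed effects stayed between log2 4 and 15.33, 33.0% were non-additive, against 67.6% of 2118 outside that range. Arrays shared between the single effects and the interaction do not either, as 96.9% of signs stayed opposite with separate arrays (92.3 to 98.2% over 100 divisions, with a median of 4314 probe sets). A saturating response of the array within its range was not tested, and neither was a biological explanation.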

How the results depend on the processing

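The fit that left out together the array of each group least like its group and the test of non-additivity on sums within the array's range were chosen after seeing the data, and all other alternatives were set in advance. No called value of a named gene reversed. Of the list tests that were called 1 did, the neural plate border list for non-additivity on sums within the range (adjusted p = 0.345), where 9 lists were called, since the members left out were those whose sum the array could not reach. Counts stayed within 1.5 times under no filter, a stricter filter, raised low values, both scalings, the trend and robust variance model and the replicate block, which gave 10264, 10513 and 9136 probe sets against GR. A change of at least 2-fold left 6330 (Pax3GR against GR), 6121 (Zic1GR), 5353 (combination), 1330 (combination against Pax3GR), 1778 (against Zic1GR) and 3921 (Pax3GR against Zic1GR), by construction, and lowered the share of higher probe sets from 54.36 to 46.75%, 55.72 to 47.51% and 54.81 to 46.89% against GR. With 1 probe set per symbol, which tests fewer, the counts were 4438, 4622, 3986, 908, 1127, 3063 and, for non-additivity, 3258. At an adjusted p of 0.01 they were 888 and 1501 (combination against Pax3GR and Zic1GR), 4516 (Pax3GR against Zic1GR) and 4238 (non-additivity), by construction. Array weights gave 4914 (combination against Pax3GR) and 10913 (Pax3GR against Zic1GR), the 2 groups alone gave 787 and the joint removal 4311 for the combination against Pax3GR. For these the cause was not tested, though Pax3GR replicate 1 had an array weight of 0.184. Lists called with an estimated correlation were 1, 1, 2, 1, 6, 3 and 4 in the order of the 7 comparisons, since it allows for members that vary together, and with fry 21 (combination against GR) and 8 (against Pax3GR), which tests a list on its own. Separate GR arrays gave 4098 shared changes of Pax3GR and Zic1GR, with fewer controls per comparison. Without 1 array the counts ranged from 9382 to 10768 (Pax3GR against GR), 9132 to 11140 (Zic1GR), 7938 to 9783 (combination), 1226 to 3038 (combination against Pax3GR, highest without Pax3GR replicate 1), 2059 to 3306 (against Zic1GR), 5947 to 7284 (Pax3GR against Zic1GR) and 6302 to 8546 (non-additivity). Lists called ranged likewise from 14 to 16, 14 to 17, 13 to 14, 4 to 8, 12 to 13, 9 to 9 and 15 to 16. Of 964 called values of the genes that the naming rule chose and of snai2.L and sox9.L, chosen outside it, 168 moved by over 1.5 times and 85 lost their call without some array, most often moved by Pax3GR replicate 1 (53). Signal near background, under log2 4, limits folds to bounds.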

Other observations

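The limma comparisons, the fits without 1 array and the test of shared list members were set in advance. All other tests in this part were chosen only after the result was seen. Some named genes were present, at log2 7 or more, on all arrays of certain groups and below 4 on all arrays of the others, and the examples were chosen after their values were seen. The pattern of 15 genes was presence in the 3 injected groups and absence from GR, among them pnhd.L, chrd.1.S, nog.L and the axon guidance gene slit2.S. The 6 genes present in Zic1GR only included pitx1.L, hesx1.L, neurog2.S and smyd1.L, a muscle methyltransferase gene. Present in Pax3GR only were c1orf216.S, fbp2, pik3r5.S, six6.L and vegfc.S (5 genes), and in Pax3GR and the combination astl3a.1.L, cdx4.L, tac1.L and tbx1.L (4 genes). GR and Zic1GR shared 5 that Pax3GR and the combination lacked, nkx2-3.L, szl.L, szl.S, tbx2.L and tbx3.S. The 2 present in GR only were neurl1.L and the ionocyte gene slc26a4.3.S, and aqp3-a was the 1 gene of Zic1GR and the combination.

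The frog has L and S copies of many genes, and 1415 pairs were measured. Where both copies were called against GR, they changed in the same direction in 389 of 459 pairs with Pax3GR (84.7%), 410 of 460 with Zic1GR (89.1%) and 326 of 369 with the combination (88.3%). Pairs of unrelated genes, drawn by shuffling 1000 times, had 50.1%, 51.0% and 50.5%. Probe sets open to cross-hybridisation were kept here. A probe set that reads both copies would raise the share for true pairs, and shuffled pairs do not control for that. Sizzled (szl.L and szl.S) and agr2.L and agr2.S moved together in each injected group where both were called. The copies of foxd3 rose to 12.17 (foxd3.L) and 10.71 (foxd3.S) in the combination, and to 10.66 and 4.78 with Pax3GR. With Pax3GR foxd3.S rose by at least 1.71-fold, or at least 1.14-fold without Pax3GR replicate 2, where it was not called (adjusted p = 0.141).

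Mesoderm list members rose in the injected explants. Members that the neural, crest, Wnt, FGF or BMP lists also hold do not account for it with Pax3GR, since without them 10 of 17 members rose and 1 fell (camera p = 0.00063, or p = 0.0298 with an estimated correlation). Mesoderm carried over at dissection stays open. The tbxt and actc1 probe sets, of genes abundant in early mesoderm and muscle, reached at most 5.42 on an injected array and 2.55 on a GR array, and no mesoderm sample shows what level it would bring. No biological explanation was tested.

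Splits of the samples into other groups of the same sizes were counted for each comparison, 100 with the real one included. The real split alone gave as many probe sets, 1 of 100, for Pax3GR against GR (10321, highest other 5808) and Zic1GR against GR (10549 and 5568). The same held for the combination against GR (9197 and 2369) and against Zic1GR (2728 and 1697), and for Pax3GR against Zic1GR (7037 and 3668). Chance can be excluded for these comparisons at that share. For non-additivity the real split gave 7510 and the highest other 2. Splits that mix the injections also break up the single effects and add them to the spread within groups. Few calls in such splits therefore do not decide whether chance accounts for the non-additive calls. For the combination against Pax3GR, 2 of 100 splits gave as many as the real 2106, and the highest other gave 3082. Chance can be excluded at that share, but a split that exceeds the real one points to a structure of the samples. Pax3GR replicate 1 stands apart in that comparison. The large counts of other splits above do not by themselves show such a structure. Splits that exchange few arrays keep much of the real difference between injections.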
